A study of Oryza sativa with 4 samples.

How the data were processed

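Rice seedlings of the cultivar Nipponbare and of the pao5 mutant were grown on 0.6% agar in darkness at 30 °C and 75% humidity for 7 days, without treatment, with 10 µM ACC or with 10 µM H2O2, per the labels' protocols. Mesocotyl RNA was extracted with TRIzol, 10 µg of RNA with an integrity number above 7.0 was selected for poly(A), and libraries with inserts of 300 ± 50 bp were sequenced in paired-end mode on a HiSeq instrument, per the labels' protocols. Each of the 4 groups held 1 library, so 3 comparisons against the single NIP library were made, with no test of a condition.

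The deposited tables, 1 per comparison, listed 44682 transcripts with RAP identifiers and the FPKM of 2 libraries, calculated by the authors. The ratio of the 2 FPKM values (fold) and its log2 were given by the authors, per the file headers. A p-value and a q-value were also given by the authors, per the file headers, and the test behind them is not given in the sources used here. The authors' call of significance matched a p under 0.05 for every transcript, and between 20769 and 20928 transcripts per table had a p of exactly 1, including genes that were very low in 1 of the libraries. The NIP values were identical in the 3 tables. Undetected transcripts held a constant of 0.0001. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8, which is a mouse build and does not go with rice identifiers, so the build and annotation behind the values remained open. The quantification tool and the annotation release are not given in the sources used here. One table held an unnamed column with 1020 identifiers that did not belong to their lines, which was not used here. The number of other columns of per-sample values left aside was 0.

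FPKM values of the transcripts of a locus were summed, which gave 37862 genes, 32507 of them with 1 transcript and 5355 with more. Gene names are the description text of the deposited tables, and 17742 genes (46.9%) had an informative one. A gene table of assembly ASM3414082v1 matched 0 identifiers and gave no names or positions, so no coordinates are given. The summing per gene and the reading of which descriptions were informative were settled after the files and the resulting counts, with and without summing, had been seen. All other main settings, the gene lists and the rule for named genes were fixed before the data were examined.

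The log2 ratio of each gene was taken between FPKM + 1 of a library and FPKM + 1 of NIP. A gene was counted when it was 2-fold or more apart with the higher library at 1 FPKM or more. For each of 32 gene lists, found by words in the descriptions, the median log2 ratio of members at 1 FPKM or more in either library was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Random lists treat genes as independent, whereas members of a family can vary together, so the percentile describes these libraries and is no test. Word searches also catch misfits, such as a TIP41-like protein among aquaporins, inhibitors among pectin genes and heat stress transcription factors among heat-shock genes.

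The named genes were PAO5 and each detected polyamine gene, the 8 described genes with the largest positive and the 8 with the largest negative ratio per comparison at 10 FPKM or more in the higher library, up to 3 members per list at 5 FPKM or more with the largest absolute ratio, and up to 8 genes 2-fold apart in the same direction in all 3 comparisons. Of these the text took about 20 to 30 per comparison, with lists in order of their absolute median. The genes lower in all 3 comparisons and oxygen-evolving enhancer protein 1 were added after their values were seen.

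The total number of reads is unknown. Relative depth was read from the low values of genes with 1 transcript, where FPKM values of 2 libraries differ by whole-read steps, within a tolerance of 0.004 on the log2 scale. The offset that aligned most transcripts held 63, 65 and 66 transcripts for pao5, ACC and H2O2, against medians of 21, 20 and 22 over other offsets, and gave depths of 95%, 85.0% and 81.1% of NIP. Offsets 2-fold apart were pooled in this search, so a library deeper or shallower by a 2-fold step would give the same reading. The FPKM summed to 664322 in NIP, 711846 in pao5, 692654 in ACC and 684468 in H2O2, and the 10 most abundant genes took 8.26%, 3.88%, 4.06% and 4.73% of these sums.

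The overlap and correlation expected from the shared control were estimated from 20 simulations of unchanged libraries of equal spread and 20 in which NIP alone varied more. The spread simulated was taken from ACC against H2O2, the pair of real libraries with the smallest spread. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter of 10 FPKM, 1.5-fold and 4-fold limits, centring on the median ratio and the authors' significance call. Chosen after seeing the data were single transcripts in place of sums, the authors' q under 0.05, rescaling without the 100 genes of highest NIP FPKM or of highest mean FPKM, and ratios between the libraries other than NIP. The code for counting and ranking was run on a simulated library made from the NIP values of 37862 genes with a random spread of 0.25 (SD of log2), below the 0.344 to 0.777 of the real pairs. All 200 genes set 4-fold or 8-fold apart were counted and 0 others were, which those settings nearly fix in advance, so this checks the code alone and says nothing about false calls between single libraries. Of 100 random lists, 5 and 7 lay outside the central 95% in these simulations. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used.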

Results

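Messenger RNA was sequenced from the mesocotyl of rice seedlings grown for 7 days in darkness. The mesocotyl is the stem-like organ between the seed and the coleoptile node, and its elongation carries the shoot through the soil. The 4 libraries, 1 per condition, came from the wild-type cultivar Nipponbare without treatment (NIP), from the pao5 mutant, from Nipponbare given 10 µM ACC, the precursor of ethylene, and from Nipponbare given 10 µM H2O2. The mutant, ACC and H2O2 libraries were each compared with the same NIP library. There were no biological replicates, so no difference could be set against a spread between samples, no test was made, and higher and lower describe these libraries alone. Levels are the authors' FPKM, summed over the transcripts of a gene, and log2 ratios are of FPKM + 1, which understates differences of low genes. Genes at 1 FPKM or more numbered 20717 in NIP, 22276 in pao5, 22724 in ACC and 22215 in H2O2. The absolute depth is unknown. The steps between low values put the depth of pao5 at 95%, of ACC at 85.0% and of H2O2 at 81.1% of that of NIP. Each of these depths is open by a 2-fold step.

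PAO5 belongs to the polyamine oxidases, enzymes that oxidise polyamines and release H2O2. Its locus, Os04g0671300, which the deposited tables describe as a probable polyamine oxidase 4, stood at 116 FPKM in NIP, 66.3 in pao5, 121 in ACC and 110.3 in H2O2. The log2 ratio to NIP was -0.80 in pao5, 0.06 in ACC and -0.07 in H2O2. The labels used here do not state the kind of mutation, and a mutant allele can still be transcribed. Of the 18 polyamine genes measured in pao5, 7 were 2-fold higher and 1 was 2-fold lower, with a median log2 ratio of 0.50, inside the range of 95% of random lists. Arginine decarboxylase 2 (Os04g0107600), which starts putrescine synthesis, stood at 0.266 FPKM in NIP, 22.04 in pao5, 8.21 in ACC and 4.64 in H2O2. An S-adenosylmethionine decarboxylase (Os09g0424300), which supplies the aminopropyl group of spermidine and spermine, stood at 2.12 in NIP, 19.02 in pao5, 22.4 in ACC and 21.4 in H2O2. Another polyamine oxidase (Os09g0368200) was at 6.31 FPKM in pao5 and at 0.132 in NIP, with 0.442 in ACC and 0.569 in H2O2. The member lower in pao5 was a spermine synthase (Os06g0528600), at 130.5 FPKM in NIP, 55.8 in pao5, 56.2 in ACC and 98.5 in H2O2. One member, a lysine-specific histone demethylase, acts on chromatin and not on free polyamines. In ACC the list had 5 of 16 members higher and 1 lower (median 0.49), and in H2O2 4 of 16 higher and 0 lower (median 0.09).

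The comparison of pao5 with NIP asked which transcripts differ when the polyamine oxidase gene is mutated. The pao5 mesocotyl had far higher levels of leaf-specific thionins, small antimicrobial peptides, and the medians of cell-wall loosening, cell division, ribosomal and pathogenesis-related genes lay above those of random lists. The same lists lay above the range in ACC and in H2O2 against the same NIP library, so they are not particular to pao5. The medians of heat-shock and AP2/ERF genes lay below those of random lists. The 6 thionin genes summed to 8.44 FPKM in NIP and 5859 in pao5. In all, 4430 genes were 2-fold higher and 1912 were 2-fold lower among 23146 compared.

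The largest positive ratios were those of thionins Os06g0513781 (1.86 FPKM in NIP, 1679 in pao5, log2 ratio 9.20) and Os06g0514100 (3.01 and 1877, log2 ratio 8.87). Thionins Os06g0513050, Os06g0513862 and Os06g0514800 reached 541, 1135 and 386 FPKM in pao5. Whether reads were shared between thionin copies was not tested, so the level of each copy is uncertain. A pair of cortical cell-delineating proteins, Os10g0551800 and Os10g0552800, stood at 618 and 713 FPKM in pao5 and at 0.526 and 1.70 in NIP. Germin-like protein 8-4 (Os08g0189300), of a family of apoplastic proteins, stood at 589 FPKM in pao5 and 1.20 in NIP. The largest negative ratios were those of a UPF0548 protein (Os04g0119300), at 41.9 FPKM in NIP and 0.563 in pao5, and of chitinase 5 (Os04g0494100), at 305 and 11.6. Chitinase IIb (Os04g0493400) was at 848 FPKM in NIP and 44.6 in pao5, and protein P21 (Os12g0630200) at 32.9 and 1.66. Each gene named in this paragraph also differed from NIP in the same direction in ACC and H2O2, though mostly by less. The UPF0548 protein stood at 10.0 FPKM in ACC and 0.321 in H2O2, chitinase 5 at 22.8 and 125.6, and Os10g0551800 at 86.7 and 7.34. The direction is therefore not particular to pao5.

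Among 32 gene lists, 14 had a median above and 2 below the central 95% of 10000 random lists matched on expression. If genes varied independently, 1.6 would lie outside by chance. Pairs without NIP also exceeded that number, with 5 lists above and 9 below in ACC over pao5. Of the expansins, which loosen cell walls, 17 of 24 members were 2-fold higher and 2 lower (median log2 ratio 2.02), with expansin-B6 (Os10g0555600) at 0.909 FPKM in NIP and 155 in pao5 and expansin-B11 (Os02g0658800) at 1.46 and 79.4. Of the xyloglucan endotransglucosylases, which cleave and rejoin wall xyloglucan, 10 of 17 were higher and 1 lower (median 1.35), led by Os11g0539200 at 2.76 and 307 FPKM. Cell division genes were higher in 62 of 108 members and lower in 3 (median 1.45). Histone H4 (Os02g0684500) stood at 1.46 FPKM in NIP and 78.4 in pao5 and histone H2A.5 (Os03g0279200) at 7.92 and 261. Cytosolic ribosomal protein genes were higher in 87 of 151 members and lower in 1 (median 1.10), with 60S protein L28-1 (Os01g0706500) at 4.46 and 29.5 FPKM. That list was fixed as a marker of the state of the RNA, and its median was also high in ACC (0.95) and H2O2 (0.83). Whether the RNA of the single NIP library differed in state was not tested. Aquaporins, which are water channels, were higher in 11 of 21 members and lower in 0 (median 1.07). Aquaporin PIP2-1 (Os07g0448800) stood at 164 FPKM in NIP and 743 in pao5.

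Pathogenesis-related genes were higher in 53 of 96 members and lower in 6 (median 1.28), with a pathogenesis-related protein 1 (Os07g0125500) at 4.96 FPKM in NIP and 752 in pao5. Class III peroxidases, secreted enzymes that use H2O2, were higher in 37 of 67 members and lower in 8 (median 1.11), with peroxidase 1 (Os05g0499300) at 1.46 and 87.5 FPKM. Jasmonate genes were higher in 22 of 41 and lower in 2 (median 1.11), with 12-oxophytodienoate reductase 5 (Os06g0215600) at 2.34 and 50.2 FPKM. Gibberellin genes were higher in 6 of 12 and lower in 3 (median 1.05), with gibberellin-regulated protein 5 (Os06g0266800) at 10.96 and 163 FPKM. Ethylene synthesis genes were higher in 6 of 14 and lower in 1 (median 0.96), with an ACC oxidase (Os05g0149400), the enzyme that makes ethylene from ACC, at 1.61 and 21.6 FPKM. The medians of auxin synthesis and transport (0.92), pectin modification (0.70), auxin response (0.61) and glutathione S-transferase genes (0.57) also lay above the random range. In the pectin list the largest ratios were those of inhibitors, with a polygalacturonase inhibitor (Os05g0104200) at 0.102 and 24.2 FPKM and pectinesterase inhibitor 8 (Os02g0537000) at 33.2 and 2.55. Auxin-responsive protein IAA12 (Os03g0633800) stood at 3.41 FPKM in NIP and 51.0 in pao5.

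Heat-shock genes were lower in 13 of 53 members and higher in 5 (median -0.65), with heat stress transcription factor A-6a (Os01g0571300) at 19.2 FPKM in NIP and 1.98 in pao5. AP2/ERF transcription factor genes were lower in 10 of 52 and higher in 8 (median -0.45), with CRF5 (Os03g0815800) at 128 and 38.5 FPKM. The other lists lay inside the random range, with medians of 0.44 for WRKY factors, 0.39 for vascular markers, 0.37 for brassinosteroid, 0.29 for NADPH oxidases, 0.26 for antioxidant enzymes, 0.18 for root markers, 0.15 for photosynthesis, 0.12 for lignin, 0.08 for seed storage, 0.04 for cellulose synthesis, 0.01 for ethylene perception, -0.02 for strigolactone, -0.06 for mesocotyl and shade regulators, -0.08 for abscisic acid and -0.19 for cytokinin genes. With only genes at 10 FPKM or more in the higher library, aquaporin (0.90), ethylene synthesis (0.71), glutathione S-transferase (0.55), auxin response (0.42) and auxin synthesis and transport genes (0.40) lay inside the random range, and cytokinin genes (-0.56) below it. Of the 2-fold genes in pao5, 69.9% were higher. With the 100 genes of highest NIP FPKM left out and each library rescaled, 3298 were higher and 2981 lower (52.5% higher), and with the 100 genes of highest mean FPKM left out instead, 3598 and 2617 (57.9%).

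**Figure D1:**
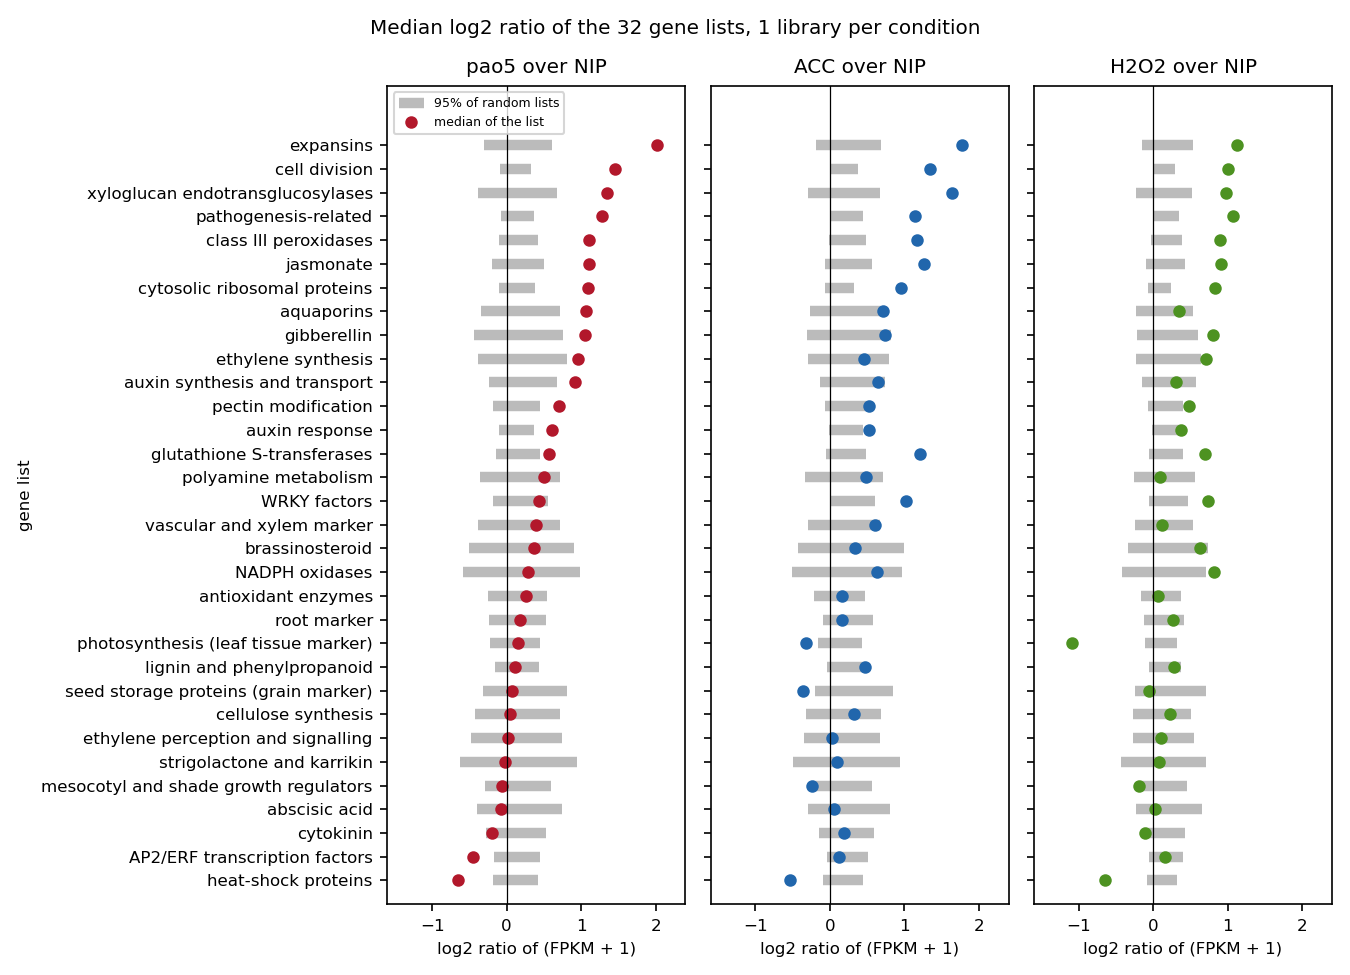
Median log2 ratio of FPKM + 1 against NIP for the 32 gene lists (points), 1 panel per comparison and 1 library per condition, over the central 95% of random lists matched on expression (grey bars). Expansins lie furthest to the right in all 3 panels, at 2.02, 1.77 and 1.12, and photosynthesis genes lie furthest to the left in the H2O2 panel, at -1.09.

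The comparison of ACC with NIP asked which transcripts differ when the ethylene precursor is supplied. The ACC mesocotyl had far higher levels of germin-like protein 8-4 and barwin, and the medians of expansins, xyloglucan endotransglucosylases, glutathione S-transferases, WRKY factors and cell division genes lay above those of random lists. Germin-like protein 8-4 also stood at 589 FPKM in pao5 and 274 in H2O2. All of these lists lay above the range in H2O2 too, and all but WRKY factors in pao5, so they are not particular to ACC. The medians of heat-shock, photosynthesis, seed storage and mesocotyl and shade genes lay below those of random lists. In all, 4669 genes were 2-fold higher and 1828 were 2-fold lower among 23472 compared.

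Germin-like protein 8-4 (Os08g0189300) stood at 1.20 FPKM in NIP and 387 in ACC (log2 ratio 7.46), and germin-like protein 3-5 (Os03g0693900) at 0.966 and 161, against 9.42 in pao5 and 26.3 in H2O2. Early nodulin-93 (Os06g0142400) was at 1.47 FPKM in NIP, 200.4 in ACC, 5.06 in pao5 and 23.4 in H2O2. Barwin (Os11g0591800), a wound-related protein, was at 1.88 and 353 FPKM, protein P21 (Os03g0663400) at 1.07 and 228, and the Dau c 1 homologue (Os12g0555000) at 9.38 and 874. The 6 thionins summed to 865 FPKM in ACC. Among the largest negative ratios, fatty acyl-CoA reductase 1 (Os04g0353600), of wax and suberin synthesis, stood at 26.8 FPKM in NIP and 0.246 in ACC, and alkane hydroxylase MAH1 (Os08g0262500), also of wax synthesis, at 14.5 and 0.0354. Non-specific lipid-transfer protein 2P (Os06g0705400) was at 269 FPKM in NIP, 11.5 in ACC, 4.78 in H2O2 and 334 in pao5. Cytochrome P450 78A9 (Os09g0528500) was at 19.4 FPKM in NIP and 0.345 in ACC.

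Of the 32 lists, 11 lay above and 4 below the random range. Expansins were higher in 17 of 25 members and lower in 3 (median 1.77), with expansin-A2 (Os01g0823100) at 9.60 FPKM in NIP and 284 in ACC. Xyloglucan endotransglucosylases were higher in 11 of 17 and lower in 1 (median 1.65). Cell division genes were higher in 63 of 107 and lower in 2 (median 1.34), with histone H2A.6 (Os05g0113900) at 1.23 and 63.3 FPKM. Jasmonate genes were higher in 25 of 42 and lower in 0 (median 1.27), with protein TIFY 11c (Os03g0180900), a jasmonate repressor family member, at 2.68 and 36.5 FPKM. Glutathione S-transferases, which conjugate glutathione to reactive compounds, were higher in 29 of 56 and lower in 5 (median 1.21), with GSTU6 (Os10g0527400) at 0.217 and 29.3 FPKM. Class III peroxidases were higher in 35 of 62 and lower in 8 (median 1.17), with peroxidase P7 (Os06g0547400) at 8.11 and 104 FPKM. Pathogenesis-related genes were higher in 47 of 86 and lower in 5 (median 1.14), with a glucan endo-1,3-beta-glucosidase GII (Os01g0713200) at 2.57 and 93.8 FPKM. WRKY factors were higher in 24 of 45 and lower in 1 (median 1.02). WRKY76 (Os09g0417600) stood at 0.279 FPKM in NIP, 19.03 in ACC, 0.235 in pao5 and 1.27 in H2O2, and WRKY62 (Os09g0417800) at 0.160, 14.7, 1.18 and 2.26.

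Cytosolic ribosomal genes (median 0.95, 69 of 149 higher and 1 lower), aquaporins (0.72, 7 of 20 higher and 0 lower) and auxin response genes (0.52) also lay above the random range in ACC. Heat-shock genes were lower in 15 of 54 members and higher in 5 (median -0.53), although heat stress transcription factor A-2c-like (Os10g0419400) was at 8.09 FPKM in NIP and 80.4 in ACC. Photosynthesis genes were lower in 11 of 51 and higher in 5 (median -0.32), with chlorophyll a-b binding protein 2 (Os01g0600900) at 5.19 and 89.9 FPKM in the other direction. Seed storage genes were lower in 4 of 16 and higher in 1 (median -0.36), with late embryogenesis abundant protein 18 (Os04g0589800) at 8.93 and 1.22 FPKM. Mesocotyl and shade regulators had a median of -0.24, below the random range, although 2 of 23 members were 2-fold higher and 0 lower, with phytochrome A (Os03g0719800), a light receptor, at 81.1 and 43.6 FPKM. The DNA helicases named PIF1 in that list are not phytochrome-interacting factors. Of the ethylene lists, synthesis (median 0.46, 6 of 13 higher and 1 lower) and perception and signalling (0.03) lay inside the range, as did AP2/ERF factors (0.12). An ACC oxidase (Os11g0186900) stood at 0.0835 FPKM in NIP and 18.6 in ACC, and ERF071 (Os01g0313300) at 3.53 and 56.6. The medians of the 17 lists inside the range ran from 0.03 to 0.75. With only genes at 10 FPKM or more in the higher library, aquaporins (0.52), auxin response genes (0.37) and mesocotyl and shade regulators (-0.17) lay inside the range, and too few seed storage genes were left. Mesocotyl and shade regulators (-0.38) also lay inside it after rescaling without the top NIP genes, as did aquaporins (0.73) with a pseudocount of 0.1. Gibberellin genes lay inside the range in ACC at 0.75 and above it under these 3 settings. AP2/ERF (-0.22) and strigolactone genes (-0.94) lay below the range and NADPH oxidases (0.97) above it with the 10 FPKM filter. Of the 2-fold genes in ACC, 71.9% were higher. With the 100 genes of highest NIP FPKM left out, 3618 were higher and 2489 lower (59.2%), and with those of highest mean FPKM left out, 3892 and 2281 (63.0%).

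The comparison of H2O2 with NIP asked which transcripts differ when the product of polyamine oxidation is supplied. The H2O2 mesocotyl had far higher levels of a pathogenesis-related protein 1 and of germin-like protein 8-3, and the medians of expansin, cell division and peroxidase genes lay above those of random lists. These lists lay above the range in pao5 and ACC as well. Photosynthesis genes were lower in most members, and the medians of heat-shock and of mesocotyl and shade genes also lay below those of random lists. In all, 3129 genes were 2-fold higher and 1150 were 2-fold lower among 22921 compared.

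A pathogenesis-related protein 1 (Os07g0125500) stood at 668 FPKM in H2O2, 4.96 in NIP (log2 ratio 6.81) and 98.8 in ACC. Its level in pao5, given above, was higher than in H2O2. Another copy (Os07g0126301) stood at 206 FPKM in H2O2 and 4.30 in NIP. The 14 kDa proline-rich protein DC2.15 (Os02g0662000) was at 0.122 FPKM in NIP and 95.9 in H2O2, and germin-like protein 8-3 (Os08g0189200) at 5.92 and 434. The 6 thionins summed to 178 FPKM in H2O2. An RNase P subunit p30 protein (Os12g0101000) was at 79.2 FPKM in NIP, 1.53 in H2O2, 43.1 in pao5 and 44.8 in ACC. Receptor-like cytoplasmic kinase 176 (Os03g0821950) was at 24.1 FPKM in NIP, 22.03 in pao5, 1.10 in ACC and 1.09 in H2O2.

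Of the 32 lists, 14 lay above and 3 below the random range. Expansins were higher in 14 of 25 members and lower in 3 (median 1.12), with expansin-B6 at 42.9 FPKM. Pathogenesis-related genes were higher in 46 of 90 and lower in 6 (median 1.07). Cell division genes were higher in 53 of 105 and lower in 0 (median 1.00), with cyclin-B1-1 (Os01g0805600), which drives entry into mitosis, at 0.482 FPKM in NIP and 30.8 in H2O2, and cyclin-dependent kinase B2-1 (Os08g0512600) at 0.376 and 22.6. Xyloglucan endotransglucosylases were higher in 8 of 17 and lower in 0 (median 0.97). Jasmonate genes were higher in 16 of 37 and lower in 1 (median 0.90). Class III peroxidases were higher in 30 of 63 and lower in 4 (median 0.89), with peroxidase 11 (Os06g0274800) at 4.65 FPKM in NIP and 85.7 in H2O2 and a peroxidase 2 (Os07g0677300) at 0.242 and 18.4. NADPH oxidases, which make superoxide at the plasma membrane, were higher in 3 of 7 and lower in 0 (median 0.82), with respiratory burst oxidase B (Os12g0541300) at 1.59 and 6.25 FPKM. WRKY factors were higher in 15 of 40 and lower in 1 (median 0.74), with WRKY71 (Os02g0181300) at 8.72 and 41.2 FPKM. Cytosolic ribosomal (0.83), gibberellin (0.80), ethylene synthesis (0.71), glutathione S-transferase (0.70), pectin (0.48) and auxin response genes (0.37) also lay above the range.

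Photosynthesis genes were lower in 30 of 51 members and higher in 2 (median -1.09), below all random lists. Oxygen-evolving enhancer protein 1 (Os01g0501800) stood at 690.0 FPKM in NIP and 168 in H2O2, and protochlorophyllide reductase A (Os04g0678700), of chlorophyll synthesis, at 51.6 FPKM in NIP, 253 in pao5, 65.5 in ACC and 9.06 in H2O2. Heat-shock genes were lower in 19 of 52 and higher in 4 (median -0.65), with the 18.1 kDa class I protein (Os03g0267000) at 18.0 FPKM in NIP and 1.79 in H2O2. Mesocotyl and shade regulators had a median of -0.19, below the random range, with 1 of 24 members 2-fold lower and 0 higher and transcription factor HY5 (Os01g0174000) at 56.6 and 31.4 FPKM. Antioxidant enzymes lay inside the range (median 0.06). Catalase-1 (Os03g0131200), which breaks down H2O2, stood at 5.35 FPKM in NIP, 7.84 in pao5, 1.75 in ACC and at the constant of undetected transcripts in H2O2, and 1-Cys peroxiredoxin B (Os07g0638400) at 0.0973 in NIP and 7.39 in H2O2. The medians of the 15 lists inside the range ran from -0.11 to 0.63. With only genes at 10 FPKM or more in the higher library, ethylene synthesis genes (0.59), WRKY factors (0.43), NADPH oxidases (0.27), auxin response genes (0.18) and mesocotyl and shade regulators (-0.18) lay inside the range, and strigolactone genes (-0.87) below it. Cellulose synthesis genes (0.41) lay above it after rescaling without the top NIP genes. Of the 2-fold genes in H2O2, 73.1% were higher. With the 100 genes of highest NIP FPKM left out, 2446 were higher and 1594 lower (60.5%), and with those of highest mean FPKM left out, 2666 and 1396 (65.6%).

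**Figure D2:**
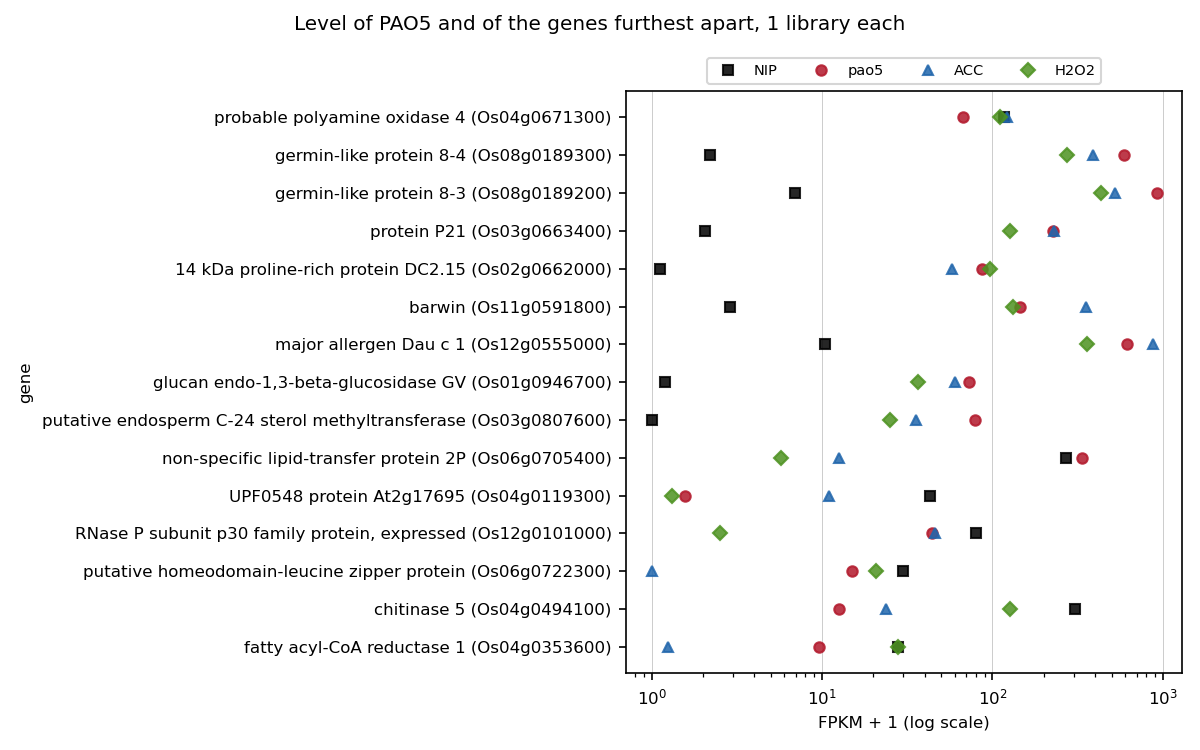
FPKM + 1 on a log axis of PAO5 (the probable polyamine oxidase 4) and of the genes furthest apart between libraries, with 1 point per library and no replicates. NIP lies far to the left of the other 3 libraries for germin-like protein 8-4, at 1.20 FPKM against 589, 387 and 274.

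In all 3 comparisons 2138 genes were 2-fold higher and 532 were 2-fold lower. After rescaling without the 100 genes of highest NIP FPKM, 1594 were higher and 869 lower in all 3. Germin-like protein 8-4, protein P21 (Os03g0663400), DC2.15, barwin, the Dau c 1 homologue and a glucan endo-1,3-beta-glucosidase GV (Os01g0946700) were among the genes with the largest common ratios. Sucrose synthase 2 (Os03g0340500), which splits sucrose, was at 158 FPKM in NIP and 27.6, 22.03 and 34.8 in pao5, ACC and H2O2, and thaumatin-like protein 1b (Os03g0244200) at 1239.8, 276, 312 and 284. These last 2 genes were chosen after their values were seen. Simulated unchanged libraries sharing 1 control gave means of 146 genes higher and 163 lower in all 3, and independent lists would share 110.2 and 6.8. The correlation of log2 ratios across genes, which are not independent replicates, was 0.85 between pao5 and ACC, 0.759 between pao5 and H2O2 and 0.860 between ACC and H2O2, against 0.501, 0.50 and 0.502 simulated. The covariances were 0.899, 0.655 and 0.718 against 0.134 simulated, which under equal spread leaves 0.765, 0.522 and 0.583. The simulated spread was taken from ACC against H2O2, the closest pair, and a larger spread would leave less and give more shared genes. Simulated unchanged libraries in which NIP alone varied more, by an amount set from the observed covariance of pao5 and ACC, gave correlations of 0.855, 0.854 and 0.854, covariances of 0.787, 0.785 and 0.787, and means of 1382 genes higher and 1681 lower in all 3. These come near the observed correlations or above them, so the correlations alone do not separate a shared response from a NIP library that varied more. Shared higher genes numbered 3294 for pao5 and ACC, 2255 for pao5 and H2O2 and 2665 for ACC and H2O2, against 854, 572 and 603 for independent lists, and shared lower genes 1059, 629 and 784 against 144, 90.7 and 86.8. Part of the excess may come from the shared NIP library, which could not be split.

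Set against each other, the 3 libraries other than NIP differed in fewer genes. ACC and pao5 were 2-fold apart in 1641 genes, H2O2 and pao5 in 2463 and H2O2 and ACC in 1420, while the pairs with NIP differed in 6342 (pao5), 6497 (ACC) and 4279 (H2O2). The list medians of these pairs, computed after the data were seen, above the random range in ACC over pao5 for 5 lists and below it for 9. The 5 were WRKY factors (0.42), glutathione S-transferases (0.37), cytokinin (0.37), lignin (0.32) and AP2/ERF genes (0.22), and the lowest of the 9 were photosynthesis (-0.45), expansin (-0.28) and auxin synthesis and transport genes (-0.27). In H2O2 over pao5, 3 lists lay above, namely AP2/ERF (0.47), WRKY (0.34) and lignin genes (0.26), and 9 below, with photosynthesis (-1.27), expansin (-0.65), auxin synthesis and transport (-0.52) and xyloglucan endotransglucosylase genes (-0.48) the lowest. In H2O2 over ACC only AP2/ERF genes (0.07) lay above and 10 lists below, among them photosynthesis (-0.63, with 20 of 51 members 2-fold lower), expansin (-0.39), xyloglucan endotransglucosylase (-0.36), glutathione S-transferase (-0.32) and cell division genes (-0.23).

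**Figure D3:**
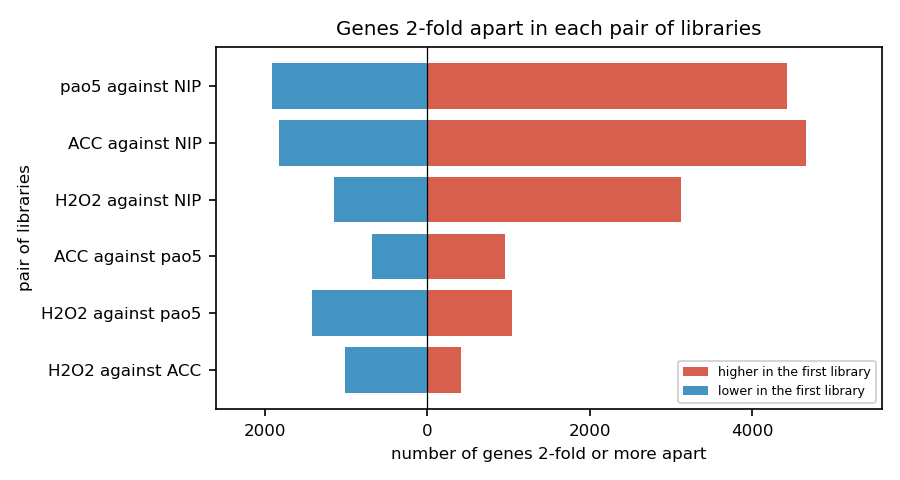
Number of genes 2-fold apart in each of the 6 pairs of libraries, 1 library per condition, with genes higher (red, to the right of 0) and lower (blue, to the left) in the first library named. The 3 pairs with NIP hold 4279 to 6497 genes and the 3 pairs without it 1420 to 2463.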

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

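The authors' q, single transcripts, both rescalings and the random lists redrawn under each alternative were chosen after the data were seen. No paired analysis was possible because each group held 1 library, and no library could be left out of a group. The absolute depth is unknown, and no replicate shows how precise any value is. No called list median took the opposite sign under any alternative run. Named genes were run only with a pseudocount of 0.1, with centring and with the rescaling without the top NIP genes. None past 2-fold changed sign, but none could. A pseudocount keeps the sign of a ratio, and centring and rescaling shift it by less than 2-fold. A pseudocount of 0.1 moved 14 of 96 list medians and 142 of 402 named ratios, the filter of 10 FPKM moved 22 list medians, rescaling without the top NIP genes moved 6, and centring, which subtracted 0.05, 0.13 and 0.10 in pao5, ACC and H2O2, moved 0. Of the 48 list medians outside the random range, 47 stayed outside it on the same side with a pseudocount of 0.1, 34 with the filter of 10 FPKM and 47 after that rescaling, and those that did not are named with their comparison. That rescaling brought the median ratio of genes at 1 FPKM or more in both libraries to -0.17, -0.06 and -0.05. The ratios of a comparison moved by nearly the same amount, and the redrawn random lists moved with them. The 47 calls kept after rescaling were therefore nearly fixed in advance. Lifting the filter changed no count, since a 2-fold gene at this pseudocount reaches 1 FPKM in any case.

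Genes higher and lower in pao5, ACC and H2O2, in that order, numbered 2328 and 954, 2195 and 912, and 1236 and 455 with a pseudocount of 5, which shrinks the ratios of low genes. A 1.5-fold limit gave 7216 and 4421, 7768 and 3908, and 6079 and 3137, and a 4-fold limit 1304 and 213, 1307 and 167, and 724 and 80. In the authors' deposited table, a q under 0.05 was held by 1354 and 576, 1211 and 564, and 637 and 274 transcripts, and the significance call was held by 2776, 2496 and 1730 higher and 1841, 1931 and 1220 lower ones, and the cause was not tested. The filter of 10 FPKM, which leaves fewer genes, gave 2562 higher in pao5, 2453 in ACC and 1447 in H2O2, with 745 lower in H2O2. Single transcripts gave 1837 lower in H2O2, and rescaling without the top NIP genes gave 2981 lower in pao5, and the cause was not tested.

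Genes 2-fold in all 3 comparisons numbered 827 higher and 245 lower with a pseudocount of 5, 1410 higher with the filter of 10 FPKM, and 1594 higher and 869 lower after rescaling without the top NIP genes, and the cause was not tested. Genes 2-fold apart from NIP numbered 3282 (pao5), 3107 (ACC) and 1691 (H2O2) with a pseudocount of 5 and 3880, 3747 and 2192 with the filter of 10 FPKM. Between the other libraries they numbered 595 (ACC and pao5), 1058 (H2O2 and pao5) and 469 (H2O2 and ACC) with a pseudocount of 5, and 819, 1415 and 687 with the filter. Under both settings each pair with NIP held more genes than each pair without it.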

Other observations

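The tests of NIP depth, of a deviation of NIP alone, of stage or handling against a shared response, and of leaf tissue were chosen only after the result was seen, as were the share of isoform transcripts and the search of annotation terms. Of 624 terms of 20 to 300 genes in the deposited annotation, which overlap in genes, 185 in pao5, 209 in ACC and 221 in H2O2 lay outside the central 95% of random lists. If genes varied independently, 31.2 would lie outside by chance. Terms are given here from the 25 with the highest and the 25 with the lowest mean of the 3 medians. Very-long-chain 3-ketoacyl-CoA synthases, which elongate fatty acids for waxes and suberin, had median log2 ratios of 1.5 in pao5, 0.83 in ACC and 0.59 in H2O2 over 23 genes. The 24 genes of the proteasome core, the chamber that degrades tagged proteins, had medians of 1.18, 0.99 and 0.75. Genes of oxalate decarboxylase activity, a term given to germin-like proteins, had medians of 1.02, 1.34 and 0.99 over 26 genes, and the 44 of chitinase activity 0.97, 1.35 and 0.89. The chitinase term held genes in both directions in pao5, with 22 members 2-fold higher and 4 lower, among them chitinase 5 as described above.

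Lower terms included the thylakoid lumen, the inner space of plastid membranes, with medians of -0.43 in pao5, -1.10 in ACC and -0.92 in H2O2 over 34 genes. The 24 genes of mRNA polyadenylation had medians of -0.59 in pao5 and -0.44 in ACC, while that in H2O2, -0.05, lay inside that range. The 27 of siRNA production had medians of -0.42, -0.19 and -0.18. The 52 genes annotated to the response to hydrogen peroxide had medians of -0.19 in pao5, -0.35 in ACC and -0.23 in H2O2, and in pao5 10 of them were 2-fold higher and 9 lower. The other medians of terms given here lay outside the range.

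The NIP library stood apart from the other 3 libraries. For a few abundant genes taking its reads, the number of genes apart could decide little. Rescaling shifts all ratios nearly alike, which trades higher genes for lower ones and hardly changes their number. With the top NIP genes left out, 6279 genes were 2-fold apart between pao5 and NIP, against 6342 with them. The split did move, from 4430 higher and 1912 lower to 3298 and 2981. The number apart thus did not depend on the top NIP genes, while part of the excess of higher genes may come from them. A shallower NIP library could not be decided on, since the depth of the others, at most 95% of NIP, is open by a 2-fold step. NIP also had the most undetected transcripts, 10720 against 9280 in pao5, 9095 in ACC and 9505 in H2O2. Noise of low genes was argued against by the spread at 50 FPKM or more, at least 0.751 with NIP and at most 0.559 without it. A deviation of NIP alone, with no relation among the other 3 libraries, puts r near 0 across genes for 2 ratios that share no library. It was argued against by r = 0.449 for pao5 minus NIP with ACC minus H2O2. The value was 0.263 for ACC minus NIP with pao5 minus H2O2 and -0.134 for H2O2 minus NIP with pao5 minus ACC. These values show some relation among the libraries and do not argue against a deviation of NIP beside it. A difference in stage, harvest or handling of the single NIP sample and a response shared by the mutant and both treatments cannot be told apart, since both allow the correlation of 0.85 between the pao5 and ACC ratios and there is only 1 NIP library. A second NIP library would be needed.

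Photosynthesis genes were lower in the H2O2 library. Of the 39 members at 20 FPKM or more in NIP, 100% lay below 0 (median -1.22, quartiles -1.58 and -0.97), as less leaf tissue in that sample would give. The same members had medians of 0.15 in pao5 and -0.37 in ACC. Wider annotation terms were nearly as low in ACC as in H2O2. The 75 genes of the photosynthesis term had medians of -0.08 in pao5, -0.65 in ACC and -0.80 in H2O2. The 131 of the chloroplast thylakoid had -0.35, -0.84 and -0.86. The 29 of chlorophyll binding did differ, with 0.53, -0.11 and -1.13. The 6 genes described as leaf-specific thionins went the other way, summing to 8.44 FPKM in NIP and 178 in H2O2. Choosing members by their NIP level favours ratios below 0, and 2 members under that level were 2-fold higher in H2O2, a ribulose bisphosphate carboxylase small chain (19.8 FPKM in NIP and 51.3 in H2O2) and a photosystem II 10 kDa polypeptide (Os07g0147500, 9.24 and 31.6). Another gene of the latter description, Os07g0147550, went the other way, at 27.6 and 1.90. Whether reads were shared between such copies was not tested. A lower level of plastid-related genes in general may also account for it, as 36 plastid ribosomal protein genes had a median of -0.62 in H2O2, although theirs was -1.32 in ACC and -0.33 in pao5. Both explanations remain open, as does a response to H2O2 itself, which was not tested.

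Single transcripts were in places 2-fold apart while their gene sum was under 1.5-fold apart. The 3 pairs of libraries without NIP held 2771 such transcripts and the 3 pairs with NIP 2149, so the pairs without NIP held 128.9% of the number with it. The count decides nothing, since the limit on the gene sum left 15618 transcripts that could be counted in the pairs with NIP and 22200 in those without it, and the share counted was 13.8% and 12.5%. Read assignment among isoforms of 1 gene and isoform use that differs between conditions therefore cannot be told apart here.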
